A study of Mus musculus with 46 samples.

How the data were processed

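Single GABAergic neurons of mouse frontal cortex were sequenced in libraries that pooled up to 16 cells, each cell under its own barcode, after linear amplification of RNA as described in the labels. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.7 to mm9. The deposited table holds expected counts made by the authors for 23335 genes in 584 cells. Of the values above 0, 4.07% were not whole within a tolerance of 1e-06, in 1678 genes with 12.0% of all counts, and 3813 genes had no count. Whether these values count reads or distinct molecular tags is not given in the sources used here, so intervals and floors cover counting error only. Gene symbols are used as the table gives them, and genomic coordinates were not used here. Rn45s took 0.786% of counts. Genes with a row identical to that of another gene number 75 among those with a total of at least 50, and named genes that share reads with another gene are said to be uncertain. The floor of a type is 3 counts over the type, expressed in CPM (counts scaled to library size).

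Samples were grouped by labelled cell type, animal, sex, age and flow cell. The labels number 18 animals, whereas the series description mentions 4, and they give animal 14 ages of 40 and 58 days. All samples carry the same statement of tamoxifen induction on embryonic day 17.5, which applies to the inducible Nkx2-1 driver. Numbers in the sample titles only count the libraries of a group: deviations of libraries with the same number correlated across types at a median of -0.0012 (range -0.056 to 0.039 over 91 pairs), so they were not used to pair samples.

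The choice of replicate was changed after the data were seen. Of 190 pairs of libraries of a type, 8 agree within sampling noise, with a ratio of the observed to the expected squared difference between 1.15 and 1.46, where data simulated with no difference gave 0.975. All 8 pairs were a PV basket library labelled male and one labelled female, under the same index in neighbouring lanes, whereas the other PV basket pairs started at 7.55. PV basket animals 7 and 8, and animals 9 and 10, were therefore summed as 1 replicate each. Whether such a pair is a single pool is not stated in the labels. The fit has 16 replicates and 9 residual degrees of freedom, and the planned fit with 18 labelled animals is given as an alternative. The comparison of PV basket cells by labelled sex used the labelled animals, as planned.

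Counts were summed over cells per replicate, rounded, and tested in R 4.3.3 with edgeR 4.0.16: trimmed-mean (TMM) scaling, filterByExpr by type (15533 genes kept), and the quasi-likelihood test with robust prior, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.381, a coefficient of variation of 61.7%, with prior degrees of freedom of 4.42 to 5.14. In 1 fit over 7 types, each type was compared with the mean of the other 6, 4 pairs of types were compared directly, and a joint test asked for any difference between types. Folds are ratios of a type's mean CPM to the mean of the other 6 type means. Fitted log2 fold changes are given only with counts in every type and average those 6 on the log scale, so can differ from folds. With no count in the lower group the fold is a lower bound against the floor, and with 1 to 3 only levels are given.

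Named genes followed a rule. The 7 driver genes were always named. For each type, the 12 largest positive and 4 largest negative log2 fold changes were taken among genes with an adjusted p under 0.05 and a mean of at least 50 CPM in the higher group, if every replicate of the type lay above the highest mean of any other type (on the lower side, below the mean of the others). For each pair of types, 10 genes per side were taken by the same threshold and level, if the replicates of both types did not overlap. Separation of replicates in these genes was thus set by the rule. This gave 192 results in 167 genes, and 1878 genes without a usual symbol were passed over. Members of lists named beyond this rule come from lists that were fixed in advance. Results for some genes are not reported here. Lists and families, alternatives, and this rule were set before the data were examined, except where stated otherwise.

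Lists of marker genes and 34 gene families were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation. Of 594 list and comparison pairs 109 passed, and 33 of these passed with the estimated correlation; not all of the others are described. With the scaling of DESeq2 in place of TMM, the net direction of a list turned in 5 of 616 pairs, and 0 called members changed sign. The 5 were cadherins in deep chandelier cells, cadherins, transcription factors and RNA splicing between upper and deep chandelier cells, and neuropeptides between Martinotti and long-projecting cells, and no direction is given for them in these comparisons. Families were compared with 10000 random lists matched on mean expression in 20 bins, by a two-sided permutation p. Cells were assigned to the type with the highest Spearman correlation, with the cell's own replicate left out, against 100 random lists per family. Mitochondrially encoded genes were listed but are absent from the table.

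Alternatives were DESeq2 1.42.0, its scaling within edgeR, other filters on genes and cells, leaving out each animal or pair, library sums with and without blocks, equal weight per cell, animal 14 split by age, sex as a covariate, thinning, an adjusted p of 0.01, 18 labelled animals, a spread set for each type, and omission of 3 libraries with another cell type. Simulation with the same replicates tested the procedure, for the simulated spread only. For Martinotti cells edgeR recovered 5.97% of 2-fold, 34.3% of 4-fold and 72.7% of 8-fold changes with 6 false calls (7.41% of calls). DESeq2 recovered 14.9%, 55.2% and 92.4% with 53 (32.9%). Of 8-fold changes edgeR recovered 95.5% for long-projecting cells and 33.3% between upper and deep chandelier. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.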

Results

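RNA was counted in 584 single GABAergic neurons from mouse frontal cortex, in 46 libraries that each pooled 7 to 16 cells under separate cell barcodes. Driver crosses named 7 types. Sst with Calb2 marked Martinotti cells (62 cells, 4 libraries), Vip with Calb2 marked interneuron-selective cells (63 cells, 4 libraries), and Vip with Cck marked CCK basket cells (64 cells, 4 libraries). Pvalb marked PV basket cells (127 cells, 16 libraries as labelled), and Nkx2-1 with tamoxifen induction marked chandelier cells of upper layers (80 cells, 5 libraries) and of deep layers (52 cells, 4 libraries). Sst with Nos1 marked long-projecting cells (136 cells, 9 libraries). The labels number 18 animals, 2 per type except for 4 each in PV basket and long-projecting cells. PV basket animals 7 and 8 were counted as 1 replicate, and so were animals 9 and 10, because their libraries agree within sampling noise in pairs. This left 16 replicates, with n = 4 in long-projecting cells and n = 2 in each other type.

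Cells held 8574 to 707657 counts, with a median of 98298 counts and 9930 detected genes. Libraries held 530927 to 4568242 counts and replicates 1203737 to 12324142. The median cell total was lowest in interneuron-selective cells at 42258 and highest in CCK basket cells at 155732. It was 62608 in upper chandelier, 86145 in deep chandelier, 107782 in Martinotti, 122095 in long-projecting and 130761 in PV basket cells. A gene with no count in a type could have reached a level between 0.141 CPM (counts scaled to library size) in PV basket cells and 0.850 CPM in interneuron-selective cells, the floor that 3 counts over the type set. Labelled sex, age and flow cell mostly followed type. Martinotti, interneuron-selective and upper chandelier cells came from animals labelled female, CCK basket, deep chandelier and long-projecting cells from animals labelled male, and PV basket cells from both. Only Martinotti with interneuron-selective cells, and upper chandelier with long-projecting cells, shared a flow cell, so sequencing batch and type could not be told apart elsewhere. Replicates of a type correlated at 0.762 to 0.936 over log2 CPM across genes, with a median of 0.906, and replicates of different types at 0.651 to 0.853, with a median of 0.762.

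The cells of a library had nearly the same profile. Cells of 1 library differed by 1.02 to 1.62 times the sampling noise, with a median of 1.15, whereas libraries of 1 type differed by 4.67 to 148 times, apart from the 8 PV basket pairs at 1.15 to 1.46. In PV basket cells, 76.6% of cells from animals labelled female and 69.8% of those labelled male carried counts of both Xist, which is expressed from the inactive X chromosome, and the Y-linked Eif2s3y. The share was at most 7.81% in any other type. All tests therefore compared sums per replicate, never cells.

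**Figure D1:**
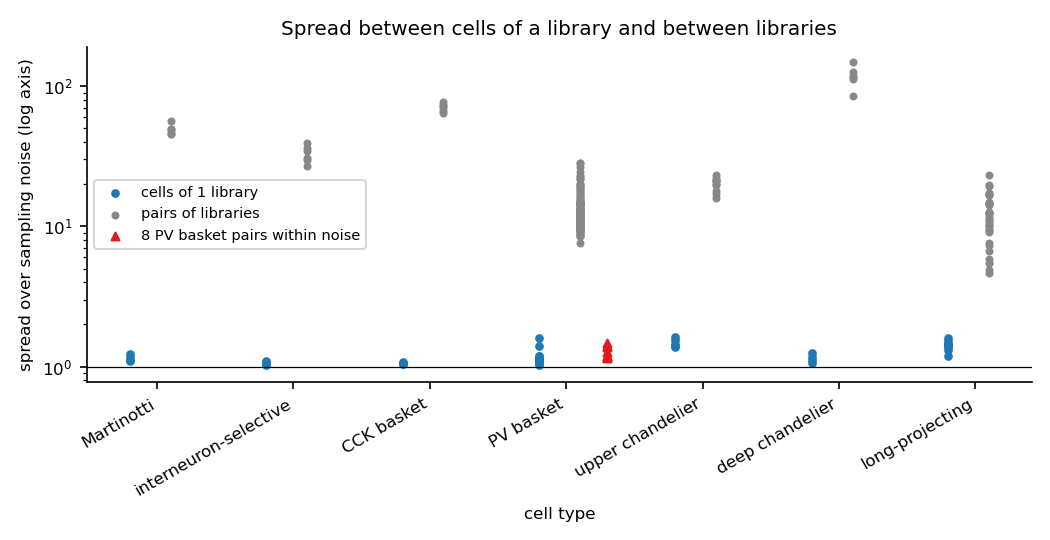
Ratio of the observed difference to sampling noise (log axis) for cells of 1 library (a point per library) and for libraries of 1 type (a point per pair), by cell type. Cells of a library lie at 1.02 to 1.62, the 8 PV basket library pairs at 1.15 to 1.46, and all other pairs of libraries at 4.67 or higher. The ratio grows with counts, which are larger in libraries than in cells.

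The 7 driver genes were examined first, to see where the genes used to label the cells were themselves expressed. Sst reached 1451 ± 327 CPM (SD, n = 2) in Martinotti and 2409 ± 429 CPM (SD, n = 4) in long-projecting cells, and at most 1.53 CPM elsewhere. Vip was highest in CCK basket cells at 4476 ± 419 CPM (SD, n = 2) and reached 2184 ± 363 CPM (SD, n = 2) in interneuron-selective cells. It also reached 409 ± 579 CPM (SD, n = 2) in deep and 51.1 ± 72.3 CPM (SD, n = 2) in upper chandelier cells, where 1 library of each type carried it. Calb2, which encodes calretinin, was highest in interneuron-selective cells at 381 ± 42.1 CPM (SD, n = 2), with 200 ± 139 CPM (SD, n = 4) in long-projecting, 98.9 ± 5.37 CPM (SD, n = 2) in Martinotti and 75.5 ± 94.8 CPM (SD, n = 2) in CCK basket cells. Cck reached 2059 ± 950 CPM (SD, n = 2) in CCK basket cells and 220.4 to 524 CPM in interneuron-selective, PV basket and both chandelier types. Single libraries raised this in deep chandelier cells (library 4 at 1375 CPM, the others at 73.6 to 342 CPM) and in interneuron-selective cells (library 2 at 1113 CPM, the others at 148 to 454 CPM). Pvalb, which encodes parvalbumin, was highest in PV basket cells at 999 ± 104 CPM (SD, n = 2), followed by upper chandelier cells at 394 ± 130 CPM (SD, n = 2) and deep chandelier cells at 254 ± 93.4 CPM (SD, n = 2). In deep cells library 1 had no count, library 2 stood at 553 CPM and the others at 172 and 165 CPM. Nkx2-1 was expressed at 71.4 ± 4.33 CPM (SD, n = 2) in upper and 33.3 ± 20.8 CPM (SD, n = 2) in deep chandelier cells, and at 7.92 to 20.01 CPM in the other types. Library 3 raised the deep chandelier mean: it stood at 60.2 CPM, and the other 3 deep libraries at 15.0 to 16.5 CPM, within the range of the other types. Nos1 reached 147 ± 8.83 CPM (SD, n = 4) in long-projecting cells and at most 16.7 CPM in any other type. All 7 driver genes differed between types. Because drivers defined the types, their levels and those of lists that contain them are not independent evidence of type identity.

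**Figure D2:**
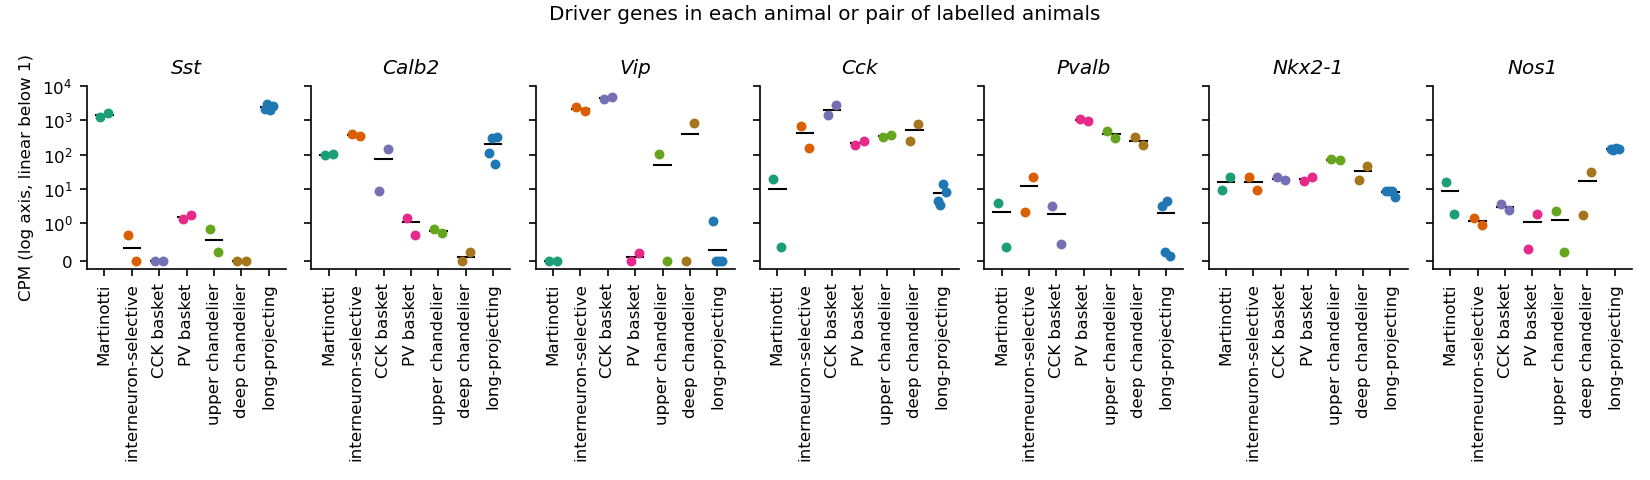
Level in CPM of the 7 driver genes (log axis, linear below 1) by cell type; each point is a labelled animal, or a pair of PV basket animals, and lines are means. Sst is high only in Martinotti and long-projecting cells, Vip in CCK basket and interneuron-selective cells, with 1 raised point in each chandelier type.

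Martinotti cells, which are known for axons that reach layer 1, were set against the mean of the other 6 types to find genes that mark them. Chst15, a chondroitin sulfotransferase gene, averaged 211 ± 14.0 CPM (SD, n = 2) against 7.69 CPM in the other types, 27.4-fold higher. Hpse, which encodes heparanase, averaged 107 ± 2.15 CPM (SD, n = 2), 31.0-fold higher, and the vesicular zinc transporter gene Slc30a3 averaged 447 ± 37.2 CPM (SD, n = 2), 15.4-fold higher. The natriuretic peptide gene Nppc was 18.0-fold higher at 51.3 ± 6.32 CPM (SD, n = 2), and the metalloprotease gene Adamts18 was 20.9-fold higher at 75.9 ± 8.86 CPM (SD, n = 2). The potassium channel gene Kcnk13 was 8.17-fold higher and Casp2 8.81-fold higher. The log2 fold changes were 5.66 ± 0.64 (SE) for Hpse, 5.62 ± 0.79 for Nppc, 5.06 ± 0.70 for Adamts18 and 4.35 ± 0.55 for Kcnk13. Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 2.76e-05 for Chst15, 0.000136 for Hpse, 0.000363 for Kcnk13, 0.000755 for Adamts18, 0.000871 for Nppc, 0.00272 for Slc30a3 and 0.00417 for Casp2. Timp3, at 143 ± 125 CPM (SD, n = 2), passed with an edgeR adjusted p of 0.0019 but not without animal 1 (0.0725), and Cbln4 passed at 0.0135 but not without animal 1 (0.0927). Calb1 passed at an edgeR adjusted p of 0.0426 and failed in 12 of the 20 leave-one-out fits, where it ranged from 0.0629 to 0.259. On the lower side, the transcription regulator gene Id2 had no count in Martinotti cells and was at least 792-fold lower than the mean of the other types, a mean that deep chandelier cells raised. It failed with a spread set for each type. Sez6 averaged 0.186 CPM in Martinotti cells against 184 CPM elsewhere.

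Of 15533 genes tested, 870 passed an adjusted p of 0.05 in Martinotti cells, 607 higher and 263 lower, whereas DESeq2 gave 831 higher and 887 lower. The count was 1433 with 18 labelled animals and 365 with a spread set for each type. Without animal 2 the count was 316, without animals 7 and 8 it was 562, without animals 9 and 10 it was 555, without animal 11 it was 1330 and without animal 12 it was 1577. Within the flow cell shared with interneuron-selective cells, 8 of the 16 named genes passed, in a direction that the rule for naming them had largely set. All 9 Martinotti marker genes were higher, also when adjusted over the list alone, among them Reln at 981 ± 291 CPM (SD, n = 2), Grin3a at 685 ± 130 CPM (SD, n = 2) and Elfn1 at 684 ± 114 CPM (SD, n = 2), with a camera adjusted p of 1.94e-41 and of 8.89e-06 with an estimated correlation. Medial ganglionic eminence lineage genes, which mark the embryonic origin of Sst and Pvalb neurons, were higher in 5 of 8 (5 when adjusted over the list alone), with Sox6 at 324.5 ± 50.2 CPM (SD, n = 2) and Lhx6 at 75.4 ± 15.7 CPM (SD, n = 2). Ionotropic glutamate receptor genes were higher in 5 of 19 and lower in 0 (6 and 1 when adjusted over the list alone). Among them were the AMPA receptor gene Gria1 at 4551 ± 206 CPM (SD, n = 2), log2 2.17 ± 0.21, and Grik3 at 372 ± 23.1 CPM (SD, n = 2). Voltage-gated calcium channel genes were higher in 7 of 23 and lower in 1 (10 and 2 when adjusted over the list alone), led by Cacng3 at log2 3.08 ± 0.42 and including Cacnb4 at 728 ± 65.3 CPM (SD, n = 2). Neuropeptide genes were higher in 8 of 27 and lower in 4 (10 and 5 when adjusted over the list alone), including Vgf at 1177 ± 553 CPM (SD, n = 2), log2 3.90 ± 0.26, Npy at 3561 ± 467 CPM (SD, n = 2) and Crhbp at 1854 ± 67.1 CPM (SD, n = 2). Camera adjusted p with an estimated correlation was 0.00358 for the lineage genes, 0.0382 for the glutamate receptors, 0.00737 for the calcium channels and 0.044 for the neuropeptides.

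Interneuron-selective cells, which carry Vip and calretinin and are known to contact other interneurons, were set against the other 6 types in the same way. The RNA-binding protein gene Rbm38 averaged 184 ± 58.0 CPM (SD, n = 2) against 2.65 CPM in the other types, 69.6-fold higher. Sez6, which encodes a seizure-related membrane protein, averaged 674 ± 398 CPM (SD, n = 2), 9.48-fold higher, with a log2 fold change of 5.20 ± 0.34 (SE). The nicotinic receptor gene Chrna4 was 17.53-fold higher at 213 ± 101 CPM (SD, n = 2), the regulator of G-protein signalling gene Rgs16 14.6-fold at 124 ± 52.2 CPM (SD, n = 2), and the transcription regulator gene Prdm8 11.5-fold at 142 ± 61.1 CPM (SD, n = 2). The homeobox gene Prox1 averaged 92.5 ± 9.68 CPM (SD, n = 2) and the cerebellin gene Cbln2 1881 ± 205 CPM (SD, n = 2), 8.37-fold and 7.61-fold higher. Prox1 also stood at 56.9 CPM in CCK basket cells. The proton-gated channel gene Accn4 was 9.52-fold higher, Cpne2 6.17-fold, the neuropeptide Y receptor gene Npy2r 4.70-fold and Calb2 itself 6.07-fold. Npy2r also reached 64.8 ± 91.6 CPM (SD, n = 2) in deep chandelier cells. There animal 12 stood at 129.6 CPM, above the 87.1 ± 22.2 CPM (SD, n = 2) of interneuron-selective cells, and animal 11 at 0. The edgeR adjusted p was 1.81e-06 for Sez6, 0.000127 for Rbm38, 0.00015 for Calb2 and 0.000286 for Prox1. It was 0.000566 for Cbln2, 0.00196 for Cpne2 and 0.0105 for Npy2r. On the lower side, Mpped1 had no count and was at least 268-fold lower, and the peptide gene Cort was at least 65.95-fold lower. All of these genes passed in each of the 20 leave-one-out fits, and Cort failed with a spread set for each type. Adora1 and Gabrd also had no count and passed, but not without animal 3 (edgeR adjusted p = 0.105 and 0.11) or animal 4 (0.138 and 0.15).

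In interneuron-selective cells 1556 genes passed, 890 higher and 666 lower, whereas DESeq2 gave 1219 higher and 1269 lower. A spread set for each type gave 508. The count was 966 without animal 3, 756 without animal 4 and 2363 without animal 12. Against Martinotti cells on the same flow cell, 8 of the 16 named genes passed, again with their direction largely set by the rule. All 8 interneuron-selective marker genes and 6 of 7 caudal ganglionic eminence lineage genes were higher, the same numbers as when adjusted over the list alone. The lineage genes, which mark the embryonic origin of Vip neurons, included Adarb2 at 3758 ± 645 CPM (SD, n = 2), log2 4.14 ± 0.32, and Npas1 at 158 ± 64.5 CPM (SD, n = 2). Camera adjusted p with an estimated correlation was 0.0179 for the markers and 0.0259 for the lineage genes. Metabotropic glutamate receptor genes were higher in 3 of 7 (4 when adjusted over the list alone), with Grm8 at 244 ± 40.4 CPM (SD, n = 2), log2 2.497 ± 0.347, and Grm7 at 668 ± 121 CPM (SD, n = 2), and camera gave an adjusted p of 0.0427 with an estimated correlation. Of 8 genes shared by GABAergic neurons 3 were lower (4 when adjusted over the list alone), among them Gad1, which fell by 1.62 ± 0.25 on the log2 scale, and Gad2, which fell by 1.65 ± 0.26. Oxidative phosphorylation genes were lower in 22 of 90 and higher in 0 (28 and 0 when adjusted over the list alone), including Atp5j at 59.1 ± 24.3 CPM (SD, n = 2), which fell by 1.84 ± 0.26 on the log2 scale. These camera calls ended with an estimated correlation, with adjusted p of 0.107 for the GABAergic genes and 0.146 for oxidative phosphorylation. Oligodendrocyte marker genes were higher in 7 of 8 (8 when adjusted over the list alone), and library 3 of animal 4 carried nearly all of their counts.

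CCK basket cells, a perisomatic type known for cannabinoid receptors, were set against the other 6 types next. Crh, which encodes corticotropin-releasing hormone, averaged 3689 ± 557 CPM (SD, n = 2) against 137 CPM elsewhere, 26.9-fold higher with a log2 fold change of 7.197 ± 0.784 (SE). The chemokine gene Cxcl14 averaged 1098 ± 279 CPM (SD, n = 2), 15.7-fold higher, and the serotonin receptor gene Htr3a 367 ± 72.5 CPM (SD, n = 2), 14.4-fold higher. The endothelin gene Edn3 averaged 67.0 ± 22.1 CPM (SD, n = 2) against 0.352 CPM, 190.3-fold higher. The protease inhibitor gene Serpine2 was 14.2-fold higher at 454 ± 73.6 CPM (SD, n = 2), log2 6.35 ± 0.49, and the transcription factor gene Sp8 27.9-fold higher at 135 ± 51.1 CPM (SD, n = 2). The water channel gene Aqp5 was 14.6-fold higher, the matricellular gene Nov 12.5-fold, the collagen gene Col15a1 12.0-fold and Vip 10.2-fold. The edgeR adjusted p was 1.22e-05 for Serpine2, 6.78e-05 for Cxcl14 and Htr3a, 0.000114 for Sp8 and 0.000163 for Crh. It was 0.00039 for Nov, 0.000561 for Edn3 and Col15a1, 0.00126 for Vip and 0.00241 for Aqp5. On the lower side, the transcription factor gene Tox3 averaged 0.163 CPM against 126 CPM. Ociad2, at 1.75 ± 0.639 CPM (SD, n = 2), was 55.3-fold lower (edgeR adjusted p = 0.00293) and failed without animal 3, at an adjusted p of 1. The substance P receptor gene Tacr1 was 369-fold lower (edgeR adjusted p = 0.021) and failed without animal 5 (0.158) or animal 6 (0.0698).

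In CCK basket cells 978 genes passed, 811 higher and 167 lower, and 1583 with DESeq2, 1513 with 18 labelled animals and 539 with a spread set for each type. The count was 549 without animal 5, 535 without animal 6 and 1570 without animal 12. All 7 caudal lineage genes were higher, also when adjusted over the list alone, with Adarb2 at 6756 ± 1055 CPM (SD, n = 2), log2 5.12 ± 0.32, Npas1 at 284 ± 77.0 CPM (SD, n = 2) and the cannabinoid receptor gene Cnr1 at 2731 ± 264 CPM (SD, n = 2). Of the medial lineage genes 3 of 8 were lower and 0 higher (4 and 1 when adjusted over the list alone): Nxph1 fell by 3.94 ± 0.47 and Sox6 fell by 2.64 ± 0.34 on the log2 scale. CCK basket markers were higher in 6 of 7 (6 when adjusted over the list alone). Monoamine receptor genes were higher in 8 of 23 and lower in 0 (10 and 1 when adjusted over the list alone), with the adrenoceptor gene Adra1b at 1020 ± 127 CPM (SD, n = 2), log2 4.83 ± 0.60, and the serotonin receptor gene Htr2c at 154 ± 36.5 CPM (SD, n = 2), log2 2.79 ± 0.43. Neuropeptide genes were higher in 9 of 27 (11 when adjusted over the list alone), including Pnoc at 325 ± 67.1 CPM (SD, n = 2). Camera adjusted p with an estimated correlation was 0.00558 for the caudal and 0.0175 for the medial lineage, 0.0168 for the markers, 0.0287 for the monoamine receptors and 0.0272 for the neuropeptides.

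PV basket cells, the fast-spiking perisomatic type, were set against the other 6 types with 127 cells from all layers. The cytochrome oxidase subunit gene Cox6a2 averaged 108 ± 0.192 CPM (SD, n = 2), 7.51-fold higher, and the guidance ligand gene Slit2 averaged 267 ± 18.5 CPM (SD, n = 2), 60.7-fold higher with a log2 fold change of 6.75 ± 0.63 (SE). The peptide gene Cartpt was 61.3-fold higher at 82.2 ± 1.87 CPM (SD, n = 2), log2 6.42 ± 0.82, Pvalb 9.00-fold, log2 6.05 ± 0.60, and the calcium channel subunit gene Cacna2d2 5.81-fold at 162 ± 2.00 CPM (SD, n = 2), log2 4.14 ± 0.49. Rgs8 averaged 0.331 ± 0.0156 CPM (SD, n = 2) against 179 CPM elsewhere, 539.5-fold lower. With edgeR, the adjusted p was 0.000138 for Cox6a2, Slit2 and Pvalb, 0.000255 for Rgs8, 0.000462 for Cacna2d2 and 0.000725 for Cartpt, and these 6 of the 16 named genes passed in each leave-one-out fit. Tac1, the substance P precursor gene, averaged 823 ± 96.4 CPM (SD, n = 2), 10.1-fold higher with an edgeR adjusted p of 0.0143. It failed without animals 7 and 8 (0.129) or animals 9 and 10 (0.0947). Deep chandelier animal 11 reached 832.4 CPM as well, and animal 12 had 0. The serine protease gene Prss23 was 69.1-fold higher (edgeR adjusted p = 0.00616) and failed in the same fits (0.0624 and 0.055), as did the neurofilament gene Nefl, 4.83-fold higher (0.182 and 0.0959). Cthrc1, 5.50-fold higher (edgeR adjusted p = 0.00233), failed without animals 7 and 8 (0.0748). Igf1, which shares reads with another gene, was 58.2-fold lower (edgeR adjusted p = 0.00114) and failed without animals 9 and 10 (0.0548).

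In PV basket cells 604 genes passed, 432 higher and 172 lower, whereas DESeq2 gave 473 higher and 589 lower. The count was 2387 in the planned fit with 18 labelled animals and 2321 with a spread set for each type. The count was 68 without animals 7 and 8, 73 without animals 9 and 10, 377 without animal 15, 394 without animal 16, 967 without animal 11 and 955 without animal 12. Of 8 PV basket markers 7 were higher (8 when adjusted over the list alone; camera adjusted p = 0.00229 with an estimated correlation). They included the potassium channel genes Kcnc2 at 1309 ± 63.8 CPM (SD, n = 2) and Kcnc1 at 454 ± 91.5 CPM (SD, n = 2), known for rapid repolarisation, Syt2 at 63.6 ± 32.8 CPM (SD, n = 2), and Cplx1 at 1774 ± 70.1 CPM (SD, n = 2), log2 1.30 ± 0.15. Voltage-gated calcium channel genes were lower in 4 of 23 and higher in 2 (8 and 3 when adjusted over the list alone): Cacna2d3 fell by 3.64 ± 0.36 on the log2 scale to 30.0 ± 2.10 CPM (SD, n = 2), and Cacna1g averaged 4.98 ± 0.700 CPM (SD, n = 2). G-protein genes and their regulators were lower in 7 of 42 and higher in 1 (9 and 3 when adjusted over the list alone), with Rgs4 as the higher gene at 102 ± 5.09 CPM (SD, n = 2). Camera adjusted p with an estimated correlation was 0.0237 for the calcium channels and 0.014 for the G-protein genes. Potassium channel genes were higher in 10 of 35 and lower in 2 (11 and 3 when adjusted over the list alone), with Kcna2 at 613 ± 10.2 CPM (SD, n = 2) and Kcna1 at 354 ± 67.6 CPM (SD, n = 2), and GABA receptor genes in 5 of 17 and 0 (9 and 2 when adjusted over the list alone), with Gabrd at 154 ± 6.11 CPM (SD, n = 2). Oxidative phosphorylation genes were higher in 14 of 90 (34 when adjusted over the list alone), among them Cox5a at 918 ± 54.1 CPM (SD, n = 2). These camera calls ended with an estimated correlation, at adjusted p of 0.145 for potassium channels, 0.075 for GABA receptors and 0.112 for oxidative phosphorylation.

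Upper chandelier cells, which are known to contact the axon initial segment, had 296 genes past the threshold, 243 higher and 53 lower. DESeq2 gave 545, 18 labelled animals 533 and a spread set for each type 538. Pthlh, which encodes parathyroid hormone-related protein, averaged 541 ± 117 CPM (SD, n = 2), 8.31-fold higher (edgeR adjusted p = 1.18e-05). The transcription factor gene Trps1 averaged 999.9 ± 118 CPM (SD, n = 2), 5.87-fold higher with a log2 fold change of 4.08 ± 0.43 (SE), and the heparan sulfotransferase gene Hs3st4 averaged 311 ± 159 CPM (SD, n = 2), 12.7-fold higher with a log2 fold change of 4.31 ± 0.40. The matrix protein gene Ibsp averaged 102 ± 87.3 CPM (SD, n = 2) against 0.248 CPM, 409-fold higher. The edgeR adjusted p was 6.88e-05 for Hs3st4, 0.000182 for Trps1 and 0.000861 for Ibsp. It was 0.00117 for the keratin gene Krt12, 20.9-fold higher. For the sarcomere gene Tcap, at 72.8 ± 10.9 CPM (SD, n = 2), it was 0.00172. The netrin receptor gene Unc5b was 8.09-fold higher at 326 ± 96.5 CPM (SD, n = 2), Pdlim3 15.0-fold and the early-response gene Egr4 11.5-fold, and they failed without animal 14 at edgeR adjusted p of 0.0824, 0.12 and 0.148. Of the 16 named genes 6 passed in each leave-one-out fit. The number of genes past the threshold was 85 without animal 13, 47 without animal 14, 164 without animal 15, 150 without animal 16, 184 without animal 17, 120 without animals 7 and 8, 131 without animals 9 and 10 and 448 without animal 12.

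Within the flow cell that upper chandelier cells shared with long-projecting cells, 14 of the 16 named genes passed, with their direction largely set by the rule for naming them. Chandelier markers were higher in 5 of 7 (5 when adjusted over the list alone), including Vipr2 at 29.8 ± 19.3 CPM (SD, n = 2) and Cpne5 at 221 ± 22.3 CPM (SD, n = 2), with a camera adjusted p of 0.00182 with an estimated correlation. Immediate early genes, which respond to neuronal activity and to tissue handling, were higher in 5 of 10 (8 when adjusted over the list alone), with Fos at 1461 ± 848 CPM (SD, n = 2), Egr1 at 595 ± 592 CPM (SD, n = 2) and Dusp1 at 149 ± 65.7 CPM (SD, n = 2). Medial lineage genes were higher in 3 of 8, with Lhx6 at 206 ± 15.1 CPM (SD, n = 2), and metabotropic glutamate receptor genes lower in 3 of 7, the same numbers as when adjusted over the list alone. Each of these 3 camera calls ended with an estimated correlation, at an adjusted p of 0.0664. Red blood cell genes were higher in 4 of 5 (5 when adjusted over the list alone), Hba-a1 at 1750 ± 2455 CPM (SD, n = 2), and library 2 of animal 13 carried nearly all of their counts; camera gave an adjusted p of 0.000115, and 0.305 with an estimated correlation.

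Deep chandelier cells had 2967 genes past the threshold, 1912 higher and 1055 lower, the largest number of the 7 types in this fit, whereas with a spread set for each type they had 469 and long-projecting cells 3264. With equal weight per cell, 770 were higher and 1812 lower. No omission of an animal or pair moved the 2967 by more than 1.5 times (2046 to 3299). In animal 12, library 4 carried Vip at 1918, Cnr1 at 911 and Adarb2 at 2031 CPM, and library 3 excitatory neuron markers at 210.3 CPM. Without this animal the count was 3185. Id2 averaged 1343 ± 1111 CPM (SD, n = 2), 24.3-fold higher, the growth factor gene Gdf10 128 ± 73.4 CPM (SD, n = 2) against 0.318 CPM, 402-fold higher, and the glucagon-like peptide receptor gene Glp1r 98.3 ± 38.8 CPM (SD, n = 2), 27.0-fold higher with a log2 fold change of 5.95 ± 0.64 (SE). The transforming growth factor gene Tgfb2 was 29.7-fold higher at 77.8 ± 41.8 CPM (SD, n = 2), log2 5.01 ± 0.54, the Wnt inhibitor gene Wif1 15.5-fold at 67.2 ± 61.6 CPM (SD, n = 2) and the transcription factor gene Mycn 11.5-fold at 144 ± 18.9 CPM (SD, n = 2). The apoptosis gene Bcl2l11 was 38.7-fold higher, the troponin gene Tnnt1 94.8-fold, the vesicle gene Rab26 22.0-fold, the sterol synthesis gene Hsd17b7 10.5-fold and the metalloprotease gene Adamts8 5.14-fold. The edgeR adjusted p was 9.84e-06 for Id2, 3.7e-05 for Hsd17b7, 4.31e-05 for Rab26 and 8.3e-05 for Glp1r, Tgfb2 and Bcl2l11. It was 9.87e-05 for Gdf10, 0.00011 for Mycn, 0.000225 for Wif1, 0.000345 for Tnnt1 and 0.00114 for Adamts8. Pcp4, a calmodulin-binding protein gene, had no count and was at least 633-fold lower, and the glycolysis gene Aldoc was at least 152-fold lower, but both failed with a spread set for each type. The prostaglandin synthase gene Ptgds and the cyclin gene Ccnd2 also had no count, but Ptgds failed in 6 leave-one-out fits (edgeR adjusted p of 0.0504 to 0.148) and Ccnd2 without animal 14 (1).

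Spread between the 2 deep chandelier animals was large, with SDs near or above the mean for Id2, Bcl2l11, Rab26 and Tnnt1. Of 8 GABAergic neuron genes 5 were higher and 1 lower, as when adjusted over the list alone, with Gad2 at 1402 ± 405 CPM (SD, n = 2), while the vesicular GABA transporter gene Slc32a1 was the lower one at 704 ± 32.6 CPM (SD, n = 2). The camera adjusted p of 0.0253 became 0.571 with an estimated correlation. Chandelier markers were higher in 4 of 7 (4 when adjusted over the list alone) and aminoacyl-tRNA synthetase genes in 13 of 34 and lower in 0 (13 and 1 when adjusted over the list alone), with Kars at 264 ± 159 CPM (SD, n = 2) and Yars at 298 ± 46.98 CPM (SD, n = 2); both camera calls ended at an adjusted p of 0.0938. Y-linked genes were higher in 3 of 4 (3 when adjusted over the list alone), with Ddx3y at 771 ± 636 CPM (SD, n = 2), in a type whose animals were labelled male, and camera gave an adjusted p of 0.0265 with an estimated correlation.

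Long-projecting cells, which are known for nitric oxide synthase and axons that leave their area, had 4 animals and 2036 genes past the threshold, 1508 higher and 528 lower, and 3264 with a spread set for each type. Npy reached 19749 ± 2950.4 CPM (SD, n = 4) and Crhbp, which encodes a binding protein for corticotropin-releasing hormone, a mean of 5418 CPM, 15.5-fold higher with a log2 fold change of 7.55 ± 0.73 (SE). The chondrolectin gene Chodl averaged 633 ± 111 CPM (SD, n = 4), 56.8-fold higher, and the amino acid transporter gene Slc7a3 563 ± 138 CPM (SD, n = 4), 87.6-fold higher. The choline transporter gene Slc5a7 averaged 109.5 ± 50.2 CPM (SD, n = 4), 13.6-fold higher, and the annexin partner gene S100a10 275 ± 55.2 CPM (SD, n = 4), 134-fold higher. Rasgef1b was 85.4-fold higher, the orexin receptor gene Hcrtr1 74.0-fold, the protease gene Bace2 46.8-fold, the pleiotrophin gene Ptn 28.0-fold, Pcp4 13.6-fold and Sst 9.95-fold. The edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 1.25e-10 for Sst, 4.48e-06 for Slc7a3, 4.54e-06 for Slc5a7, 5.61e-06 for Ptn, 1.05e-05 for Pcp4, 1.58e-05 for Crhbp, 2.31e-05 for S100a10, 4.63e-05 for Chodl and 0.000638 for Hcrtr1, and all passed in each leave-one-out fit. The zinc finger gene Zfp804a averaged 3.27 ± 1.51 CPM (SD, n = 4), 92.0-fold lower (edgeR adjusted p = 8.51e-07), and Igsf3 was 129-fold lower, falling by 6.06 ± 1.11 on the log2 scale. Crh averaged 0.490 ± 0.981 CPM (SD, n = 4) against 752 CPM, 1534-fold lower (edgeR adjusted p = 0.00144), a call that ended without animal 12 at an adjusted p of 1, and Pnoc was 87.9-fold lower (edgeR adjusted p = 0.00522), a call that ended without animal 2, also at 1. The number past the threshold was 1250 without animal 15, 1160 without animal 16 and 1222 without animal 18.

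Within the shared flow cell, 12 of the 16 genes named for long-projecting cells passed against upper chandelier cells, with their direction largely set by the rule for naming them. All 7 long-projecting markers were higher, also when adjusted over the list alone, with the substance P receptor gene Tacr1 at 1004 ± 152 CPM (SD, n = 4) and the oxytocin receptor gene Oxtr at 246 ± 75.4 CPM (SD, n = 4); the camera adjusted p was 0.000421 with an estimated correlation. Neuropeptide genes were higher in 10 of 27 and lower in 3 (11 and 3 when adjusted over the list alone), including the enkephalin gene Penk at 838 ± 169 CPM (SD, n = 4) and Cort at 186 ± 120 CPM (SD, n = 4). Potassium channel genes were lower in 10 of 35 and higher in 5 (14 and 7 when adjusted over the list alone): Kcnh7 fell by 2.66 ± 0.30 and Kcnc1 fell by 1.74 ± 0.20 on the log2 scale. Neurexins, neuroligins and related adhesion genes were lower in 10 of 50 and higher in 4 (14 and 4 when adjusted over the list alone), and Nlgn1 fell by 1.60 ± 0.14. Camera adjusted p with an estimated correlation was 0.0286 for neuropeptides, 0.0433 for potassium channels and 0.0376 for the adhesion genes. Cytosolic ribosomal protein genes were higher in 42 of 78 (55 when adjusted over the list alone), with Rpl10 at 1164 ± 136 CPM (SD, n = 4), log2 1.08 ± 0.12, but the camera adjusted p of 8.92e-12 became 0.267. Oligodendrocyte markers were higher in 4 of 8 (7 when adjusted over the list alone), and library 2 of animal 15 carried most of their counts.

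**Figure D3:**
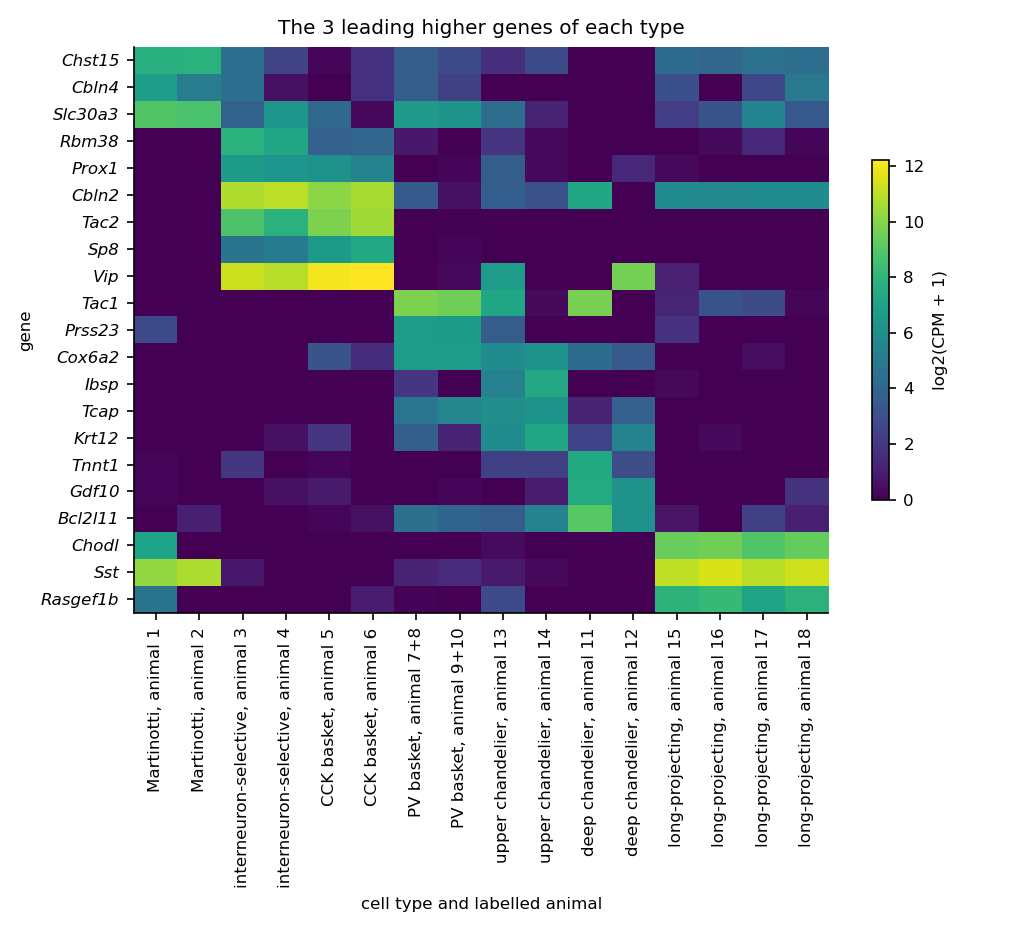
Log2(CPM + 1) of the 3 leading higher genes of each type (vertical axis) in each labelled animal or pair of PV basket animals (horizontal axis), with colour from low to high. Each block of genes is brightest in its own type, and interneuron-selective and CCK basket cells share most of their blocks.

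Upper and deep chandelier cells share a driver but differ in labelled sex, age (40 to 58 against 34 days) and flow cell. Their comparison cannot single out layer. The prostaglandin transporter gene Slco2a1 averaged 228 ± 38.0 CPM (SD, n = 2) in upper against 5.36 ± 0.691 CPM (SD, n = 2) in deep cells, a log2 fold change of 5.39 ± 0.54 (SE). Gng4, a G-protein subunit gene, was 50.3-fold higher in upper cells, the adaptor gene Sash1 25.6-fold at 484 ± 18.9 CPM (SD, n = 2) and the leucine-rich repeat gene Lrrc17 23.7-fold at 255 ± 14.4 CPM (SD, n = 2), with log2 fold changes of 5.47 ± 0.82, 4.68 ± 0.63 and 4.57 ± 0.59. The exchange factor gene Rasgrf2, at 35.7 ± 27.0 CPM (SD, n = 2) in upper and 711 ± 237 CPM (SD, n = 2) in deep cells, was 19.9-fold lower. With edgeR, the adjusted p was 0.000447 for Slco2a1, 0.0019 for Lrrc17, 0.00255 for Sash1, 0.00351 for Rasgrf2 and 0.00572 for Gng4, and these 5 of 20 named genes passed in each leave-one-out fit. With a spread set for each type only Rasgrf2 of the 5 passed. With only the compared types in the edgeR fit 0 genes passed, with 1661 at an unadjusted p under 0.05. The phosphatase gene Ptprf was 26.7-fold higher (edgeR adjusted p = 0.00939) and failed without animal 13 (0.0509). The perineuronal matrix gene Hapln1 was 13.6-fold lower (edgeR adjusted p = 0.0229) and failed without animal 11 (0.0621), 13 (0.153) or 14 (0.161). In all, 440 genes passed, 273 higher and 167 lower, and 2079 with DESeq2, 1151 with 18 labelled animals and 51 with a spread set for each type. The higher share was 62.05%, but 46.37% with DESeq2, 47.48% with its scaling, which shifted the median log2 ratio in this comparison by -0.116, 39.7% with animal 14 split by age and 3.92% with a spread set for each type, so no overall direction is given. The count was 58 without animal 13, 43 without animal 14, 198 without animal 15, 208 without animal 16, 201 without animal 17, 212 without animal 18, 192 without animals 7 and 8, 193 without animals 9 and 10 and 1343 without animal 12.

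None of the 7 chandelier markers, over all genes or when adjusted over the list alone, and none of the 7 driver genes separated upper from deep chandelier cells; Nkx2-1, at 71.4 against 33.3 CPM, had an edgeR adjusted p of 0.349. Oxidative phosphorylation genes were higher in upper cells in 13 of 90 and lower in 1 (22 and 4 when adjusted over the list alone), with Ndufa11 at log2 2.06 ± 0.38 and Cox8a at log2 1.38 ± 0.27, and Uqcrc2 fell by 1.57 ± 0.31. The camera adjusted p of 0.00201 became 0.767 with an estimated correlation.

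Upper chandelier and PV basket cells, both Pvalb-expressing, were compared to ask what sets apart these neighbours in lineage. The receptor tyrosine kinase gene Kit averaged 355 ± 87.2 CPM (SD, n = 2) in chandelier and 3.07 ± 0.494 CPM (SD, n = 2) in PV basket cells, 116-fold higher with a log2 fold change of 6.85 ± 0.66 (SE). The T-type calcium channel gene Cacna1g was 21.4-fold higher at 106 ± 7.08 CPM (SD, n = 2), log2 4.41 ± 0.47, and the calcium channel subunit gene Cacna2d3 13.7-fold higher at 412 ± 173 CPM (SD, n = 2), log2 3.78 ± 0.40. Adjusted p by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.000776 for all 3, which passed in each leave-one-out fit, as did 4 of the 20 named genes in all. In all, 62 genes passed, 41 higher and 21 lower, and 391 with DESeq2, 392 with 18 labelled animals, 944 with a spread set for each type and 676 with only these types in the fit. The count was 25 without animal 13, 12 without animal 14, 32 without animal 15, 36 without animal 16, 25 without animal 17, 23 without animal 18, 9 without animals 7 and 8, 7 without animals 9 and 10, 121 without animal 11 and 129 without animal 12. Chandelier markers were higher in 2 of 7 (5 when adjusted over the list alone), with a camera adjusted p of 0.0203 with an estimated correlation. PV basket markers were lower in 0 of 8 (3 when adjusted over the list alone), with Kcnc2 at 360 against 1309 CPM (edgeR adjusted p = 0.121), and camera went from 0.000121 to an adjusted p of 0.173.

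Interneuron-selective and CCK basket cells both carried the Vip driver, and their comparison asked what separates types that share it. Igbp1, a phosphatase-binding protein gene, averaged 3.67 ± 2.22 CPM (SD, n = 2) in interneuron-selective and 169 ± 55.8 CPM (SD, n = 2) in CCK basket cells, and fell by 5.46 ± 0.58 (SE) on the log2 scale. The actin regulator gene Arpc3 fell by 4.94 ± 0.81 to 6.54 ± 8.25 CPM (SD, n = 2). Rsph3b, which shares most of its sequence with Rsph3a, was 21.0-fold lower. On the higher side, Tmub1 averaged 239 ± 58.2 CPM (SD, n = 2) against 16.8 ± 2.26 CPM (SD, n = 2), log2 3.83 ± 0.54. By edgeR's quasi-likelihood test, the Benjamini-Hochberg adjusted p was 0.000748 for Igbp1, 0.00834 for Tmub1 and Rsph3b and 0.0125 for Arpc3, the 4 of 20 named genes that passed in each leave-one-out fit. The orphan receptor gene Gpr162 was 11.2-fold higher (edgeR adjusted p = 0.0214) and failed without animal 4 (0.0596), 5 (0.0902) or 6 (0.0741), and the transcription factor gene Sox2, 6.90-fold higher (0.0369), failed in 10 such fits (0.0579 to 0.141). With a spread set for each type, 0 of the 20 passed. In all, 209 genes passed, 51 higher and 158 lower. Only 1 passed with only these types in the fit and 4 with a spread set for each type, against 1411 with DESeq2 and 730 with 18 labelled animals. The count was 100 without animal 4, 120 without 5, 79 without 6, 102 without 13, 92 without 14, 64 without 15, 62 without 16, 69 without 17, 73 without 18, 65 without animals 7 and 8, 68 without animals 9 and 10, 704 without animal 11 and 689 without animal 12.

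None of the 7 driver genes and no gene of the interneuron-selective, CCK basket or caudal lineage lists passed between interneuron-selective and CCK basket cells. GABAergic neuron genes were lower in interneuron-selective cells in 2 of 8 (6 when adjusted over the list alone), among them Dlx1, which fell by 1.47 ± 0.31 to 175 ± 33.8 CPM (SD, n = 2). Cytosolic ribosomal protein genes were lower in 9 of 78 and higher in 0 (21 and 1 when adjusted over the list alone), and Rpl7 fell by 1.83 ± 0.19. Oxidative phosphorylation genes were lower in 6 of 90 (15 when adjusted over the list alone). With an estimated correlation the camera adjusted p was 0.338, 0.618 and 0.594, so these calls ended.

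Martinotti and long-projecting cells both carried the Sst driver, and their comparison asked what separates types that share it. Reln, which encodes the secreted protein reelin, averaged 981 ± 291 CPM (SD, n = 2) in Martinotti and 26.1 ± 10.9 CPM (SD, n = 4) in long-projecting cells, 37.6-fold higher with a log2 fold change of 5.24 ± 0.56 (SE). The cadherin gene Cdh7 was 56.2-fold higher at 153 ± 57.6 CPM (SD, n = 2), log2 5.85 ± 0.77, Kcnk13 44.7-fold, log2 5.47 ± 0.82, and Hpse 104-fold, log2 6.69 ± 1.02. Igsf3 averaged 141.5 ± 43.5 CPM (SD, n = 2), 155-fold higher, and Rasl11a 234 ± 265 CPM (SD, n = 2), 306-fold higher. The sterol synthesis gene Sc5d was lower in Martinotti cells, at 0.615 against 85.4 CPM, and fell by 6.96 ± 0.88 on the log2 scale. Slc5a7 had no count in Martinotti cells and was at least 311-fold lower. The edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p of 0.000303 for Reln, 0.000742 for Sc5d, 0.000951 for Cdh7, 0.00121 for Rasl11a, 0.0023 for Kcnk13, 0.00253 for Hpse and 0.00688 for Igsf3, and all of these passed in each leave-one-out fit. Slc7a3 was 129-fold lower (edgeR adjusted p = 0.0121) and failed without animal 2 (0.0596), and Pcp4, 38.0-fold lower (0.0272), failed without animal 15, 16, 17 or 18 (0.0606 to 0.0688). In all, 607 genes passed, 280 higher and 327 lower, with 1773 by DESeq2, 1195 with 18 labelled animals and 1900 with only these types in the fit, and the side with more genes depended on the setting (63.42% higher with a spread set for each type). The count was 186 without animal 2, 303 without animal 15, 266 without animal 16, 332 without animal 17, 303 without animal 18, 384 without animals 7 and 8, 385 without animals 9 and 10, 1139 without animal 11 and 1137 without animal 12.

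Of 9 Martinotti markers 3 were higher in Martinotti than in long-projecting cells (4 when adjusted over the list alone; camera adjusted p = 0.0365 with an estimated correlation), Elfn1 at log2 2.47 ± 0.40. Long-projecting markers were lower in 1 of 7 (6 when adjusted over the list alone): Npy fell by 2.47 ± 0.53, whereas Nos1, at 8.82 against 147 CPM, had an edgeR adjusted p of 0.0656. Ionotropic glutamate receptor genes were higher in 5 of 19 and lower in 0 (7 and 2 when adjusted over the list alone), with Gria1 at log2 2.26 ± 0.27, Gria3 at 1.88 ± 0.34 and Gria4 at 1.33 ± 0.23. Potassium channel genes were higher in 5 of 35 and lower in 2 (11 and 3 when adjusted over the list alone), with Kcnq3 at log2 1.91 ± 0.43. With an estimated correlation the camera adjusted p was 0.0901 for long-projecting markers, 0.0887 for glutamate receptors and 0.0565 for potassium channels, so these calls ended.

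PV basket cells labelled male and female were compared over the 4 labelled animals to ask whether sex changes expression within a type. By edgeR's quasi-likelihood test 0 of 15662 genes passed, 2 had an unadjusted p under 0.05, and DESeq2 called 1. Xist stood at 102 CPM in cells labelled female and 114 CPM in cells labelled male, and Eif2s3y at 31.7 and 23.9 CPM, so the libraries did not separate by labelled sex, and this comparison cannot show a sex difference.

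Across all 7 types, 3888 of 15533 genes (25.0%) differed by edgeR's quasi-likelihood test. DESeq2 gave 7080, 18 labelled animals 6468 and a spread set for each type 2174. The count was 2560 without animals 7 and 8 and 2583 without animals 9 and 10. Gene families were then compared with random lists matched on mean expression. Of 853 genes in 22 families of synaptic communication 446 differed (52.3%), as did 65 of 176 transcription factor genes (36.9%). In 11 housekeeping families 220 of 761 did (28.9%, by family 13.95% to 62.8%). Neuropeptide genes differed in 25 of 27 (92.6%) against 50.7% in matched lists, neuropeptide receptors in 22 of 34 (64.7%) against 18.0%, and voltage-gated potassium channels in 24 of 35 (68.6%) against 33.4%. Other potassium channels differed in 19 of 34 against 23.8% in matched lists, cadherins and protocadherins in 60 of 90 (66.7%) against 38.9%, secreted growth factors in 22 of 47 (46.8%) against 23.3%, and transcription factors lay above their 24.9%. In each the permutation p was 0.0002, the smallest possible (Benjamini-Hochberg adjusted 0.000971). Metabotropic glutamate receptors (6 of 7), voltage-gated calcium channels (14 of 23), synaptotagmins (12 of 22), transmitter synthesis and transport (16 of 36), neurexin-type adhesion (29 of 50), guidance (25 of 59) and G-protein signalling (23 of 42) also passed above matched lists. Mitochondrial ribosomal proteins (11 of 76), RNA splicing (19 of 98) and ubiquitin conjugation (6 of 43) passed below them. Without PV basket cells the calls of metabotropic glutamate receptors, synaptotagmins, guidance and mitochondrial ribosomal proteins ended, at adjusted permutation p of 0.0852, 0.0732, 0.0808 and 0.0988. With genes counted at an adjusted p of 0.01 that of G-protein signalling ended (0.109). By Fisher's exact test without matching those of ubiquitin conjugation and RNA splicing ended (adjusted p = 0.152 and 0.304). That test put cytosolic ribosomal proteins (49 of 78) and oxidative phosphorylation (49 of 90) above (1.95e-11 and 1.96e-08). Vesicle release machinery (30 of 69 against 41.9%) did not pass (adjusted permutation p = 0.878), nor did 16 other families.

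**Figure D4:**
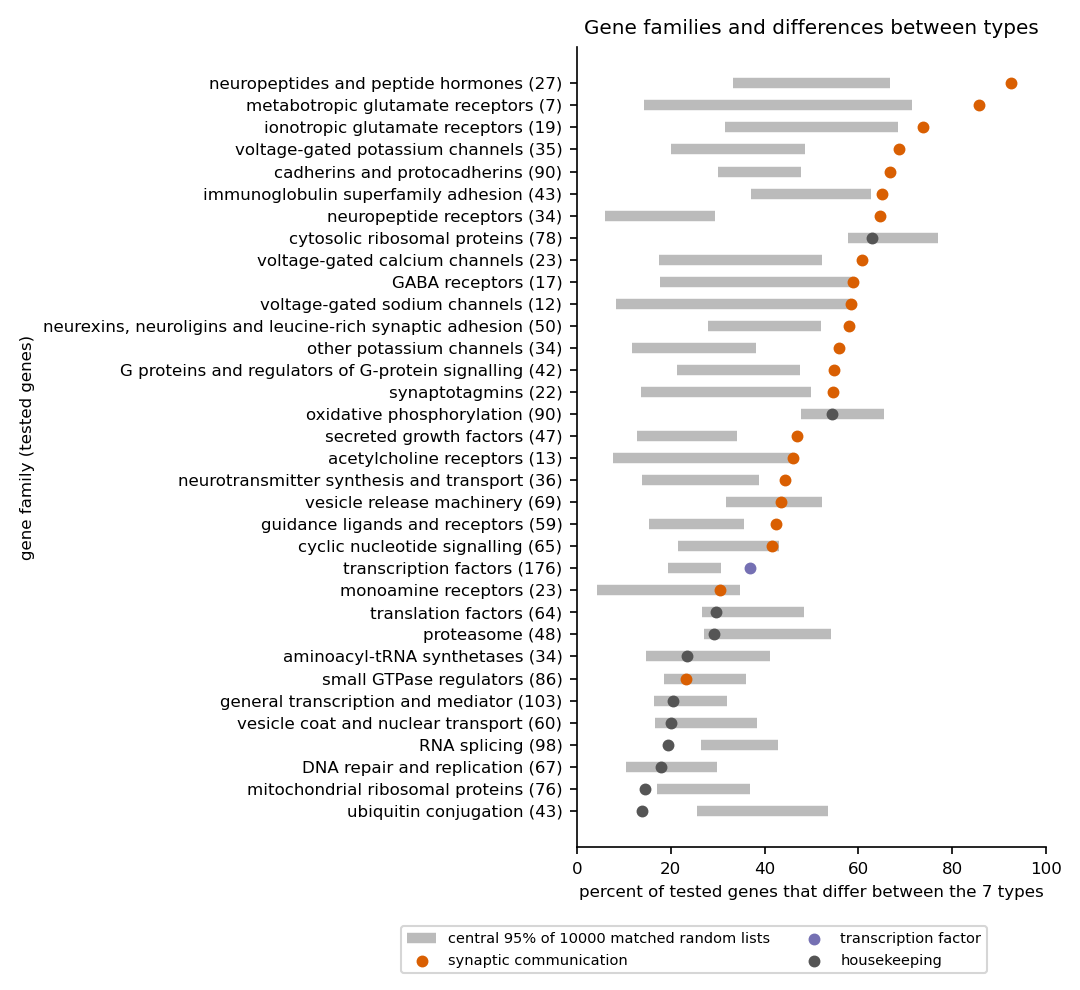
Percent of tested genes that differ between the 7 types, for 34 gene families (points, coloured by kind), with the central 95% of 10000 random lists matched on mean expression (grey bars). Neuropeptides, neuropeptide receptors and potassium channels lie above their bars, and ubiquitin conjugation, RNA splicing and mitochondrial ribosomal proteins below.

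Cells were also assigned to a type by their Spearman correlation with type profiles from other replicates, using 1 family at a time, where chance gives 14.3%. Percentages correct were averaged over the replicates of a type and then over types, so they are not shares of all cells. The median was 71.9% over the synaptic families against 49.5% for matched random lists, 74.3% against 52.2% for transcription factors, and 40.3% against 59.8% over the housekeeping families. G-protein genes reached 81.6%, neuropeptide receptors 80.6%, voltage-gated potassium channels 77.3%, calcium channels 77.25% and guidance genes 70.9%. These 5, with other potassium channels, monoamine receptors, secreted growth factors and transcription factors, were the 9 of 34 families above all 100 matched lists; with library sums in place of cells 5 were, and of the 9 only neuropeptide receptors and transcription factors remained. Cytosolic ribosomal protein genes reached 57.3% against 94.5% for matched lists. With all genes the average was 57.1%. All CCK basket, PV basket and long-projecting cells went to their own type, but all 63 interneuron-selective cells went to CCK basket and 51 of 52 deep chandelier cells to PV basket. Of 62 Martinotti cells 27 went to long-projecting and 5 to PV basket, and of 80 upper chandelier cells 34 went to PV basket. Since cells of a library share much of their profile, these shares say little beyond the libraries.

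Marker genes of other cell types were low in most libraries. Over all 7 types, 0 of 8 oligodendrocyte, 0 of 3 oligodendrocyte precursor, 0 of 6 microglia and 0 of 6 endothelial markers differed, and 2 of 7 astrocyte, 1 of 3 pericyte, 2 of 6 excitatory neuron and 4 of 5 red blood cell genes did (0, 0, 0, 0, 3, 1, 3 and 5 when adjusted over the list alone). Immediate early genes differed in 7 of 10 (9 when adjusted over the list alone), Y-linked genes in 3 of 4 and Xist and Tsix both.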

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

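All tests of explanations in this part were chosen only after the results they measure had been seen. Values are named here because a library lay far from the others of its type by Dixon's criterion, in 20 of 68 tests, where chance gives about 1 in 20.

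At the median gene, cells of a library differed by little more than sampling noise. Of PV basket cells 73.23% carried both Xist and Eif2s3y, whichever sex their library was labelled with. Signal shared between barcodes would give such cells if a pool held both sexes, which the labels do not state, and stays open as a hypothesis. Cells that are alike could share signal too, so this value cannot decide on likeness of cells in this type. In the other 6 types the lowest ratio between libraries of a type was 4.669, which cannot separate true likeness of cells from sharing, because spread added by library preparation is not known.

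Oligodendrocyte markers summed to 3466 CPM in interneuron-selective library 3 and 4666 CPM in long-projecting library 2, and red blood cell genes to 16583 CPM in upper chandelier library 2. Free RNA of the tissue is argued against, since other libraries of the same animals reached at most 3.771% of these sums. A candidate explanation is 1 cell of another type in the pool, with its RNA spread over the barcodes: 94.44% of the list genes had their highest value in a single cell column of their library. Abundant genes were Mal at 798 and 581 CPM in the first 2 libraries, and Hba-a1 at 5206 and Hbb-b1 at 3032 CPM in the third, where Hba-a2 and Hbb-b2 repeat these values in the sum. Selection of labelled cells would remove such cells, no other list holds these genes, only Mbp among the oligodendrocyte genes stood above 20 CPM in the median of the other libraries of its type (42.3 and 66.3 CPM), and no biological explanation was tested.

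Vip, a driver of other types, stood at 1918 CPM in deep chandelier library 4 and 374.3 CPM in upper chandelier library 1. Cells like the labelled CCK basket cells are argued against in the deep library: Vip reached 44.2% of the CCK basket level, while the median over 11 other named CCK basket genes was 0%. Crh there was 149.9 CPM, Cnr1 911 CPM, Adarb2 2031 CPM and Cck 1375 CPM. Whether cells like CCK basket cells or another Vip-expressing population were present stays open. In the upper library, 70% of the raised marker genes had their highest value in the column with most such genes. This cannot tell a single Vip neuron from other sources.

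The count of 2036 genes for long-projecting cells was reached by 1 of 100 splits of the 16 replicates, the real one. The highest other split gave 17. The other splits mixed types, which raises the spread within groups and lowers counts, so this cannot exclude chance for long-projecting cells.

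Further values far from the others of their type were these. Astrocyte markers were lowest in interneuron-selective library 2, at 303.2 CPM. Oligodendrocyte markers were highest at 129.6 CPM in the mean of PV basket libraries 14 and 16 and at 144.8 CPM in deep chandelier library 2. Oligodendrocyte precursor markers were highest at 105.3 CPM in interneuron-selective library 3, at 67.4 CPM in CCK basket library 3 and at 88.04 CPM in long-projecting library 2. Endothelial markers were highest at 75.8 CPM in Martinotti library 4, at 159.7 CPM in CCK basket library 3 and at 69.24 CPM in the mean of PV basket libraries 9 and 11. Pericyte markers were highest at 167 CPM in Martinotti library 4, and excitatory neuron markers at 210.3 CPM in deep chandelier library 3. Red blood cell genes were highest at 255.4 CPM in Martinotti library 4 and at 228.9 CPM in interneuron-selective library 2. Immediate early genes were highest at 628.6 CPM in the mean of PV basket libraries 9 and 11. Nkx2-1 was highest at 60.23 CPM in deep chandelier library 3.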

How the results depend on the processing

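Chosen after the data were seen were the fits with a spread set for each type and without 3 libraries with another cell type. So were those without each pair of PV basket animals and library sums in the assignment. Counts stayed within 1.5 times of those reported, in all 13 comparisons, with the scaling of DESeq2 in edgeR, no filter on genes, a mean of 20 CPM in at least 1 type, cells of low total left out, and sums thinned to the smallest total. Over all settings no named gene reversed its direction. The side with more genes turned for Martinotti with DESeq2 and with equal weighting of cells, for interneuron-selective with DESeq2 and with sex as a covariate, for PV basket with DESeq2, for deep chandelier with equal weighting of cells, and for interneuron-selective against CCK basket with only these types in the fit. For upper against deep chandelier it turned with DESeq2, with its scaling, with library sums without a block, with animal 14 split by age and with a spread set for each type. For Martinotti against long-projecting it turned with the scaling of DESeq2, a mean of 20 CPM, library sums with and without a replicate block, animal 14 split by age, thinning, an adjusted p of 0.01 and a spread set for each type, and without animal 2, 15, 16 or 18. Of 192 named results, 186 passed with DESeq2, 189 with its scaling, 182 without a filter, 140 with a spread set for each type, 118 at an adjusted p of 0.01, 169 without the 3 libraries, 192 with 18 labelled animals and 99 with sex as a covariate, and 180 of 191 passed after thinning and 40 of 79 with only the compared types in the fit. Leaving out animals or pairs left between 141 (without animal 14) and 192 (without animal 8) of them. In simulated data of 4 comparisons, edgeR recovered at most 11.9% of 2-fold changes. Except where the setting itself removes samples or raises the threshold, the cause was not tested.

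Leaving out each animal or pair in turn gave counts of 2560 to 5229 for any difference, 316 to 1577 for Martinotti, 756 to 2363 for interneuron-selective, 535 to 1570 for CCK basket, 68 to 967 for PV basket, 47 to 448 for upper chandelier, 2046 to 3299 for deep chandelier, 1160 to 2671 for long-projecting, 43 to 1343 for upper against deep chandelier, 7 to 129 for upper chandelier against PV basket, 62 to 704 for interneuron-selective against CCK basket, 186 to 1139 for Martinotti against long-projecting, and 0 to 0 for PV basket male against female. A type left with 1 replicate was assumed to vary like the others. DESeq2 gave 7080 for any difference, 1718 for Martinotti, 2488 for interneuron-selective, 1583 for CCK basket, 1062 for PV basket, 545 for upper chandelier, 2079 for upper against deep chandelier, 391 for upper chandelier against PV basket, 1411 for interneuron-selective against CCK basket and 1773 for Martinotti against long-projecting, and 1 for PV basket male against female. Library sums with the animal as a random block in limma voom gave 7062 for any difference, 1579 for Martinotti, 1750 for CCK basket, 2701 for PV basket, 701 for upper chandelier, 3617 for long-projecting, 1192 for upper against deep chandelier, 858 for upper chandelier against PV basket, 591 for interneuron-selective against CCK basket and 2129 for Martinotti against long-projecting. The equal weighting of cells gave 639 for CCK basket, 888 for upper against deep chandelier, 121 for upper chandelier against PV basket and 399 for interneuron-selective against CCK basket. An adjusted p of 0.01 gave 1623 for any difference, 245 for Martinotti, 444 for interneuron-selective, 392 for CCK basket, 198 for PV basket, 75 for upper chandelier, 1241 for deep chandelier, 1046 for long-projecting, 60 for upper against deep chandelier, 13 for upper chandelier against PV basket, 23 for interneuron-selective against CCK basket and 189 for Martinotti against long-projecting.

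With 18 labelled animals the counts were 6468 for any difference, 1433 for Martinotti, 1513 for CCK basket, 2387 for PV basket, 533 for upper chandelier, 1151 for upper against deep chandelier, 392 for upper chandelier against PV basket, 730 for interneuron-selective against CCK basket and 1195 for Martinotti against long-projecting. A spread set for each type gave 2174 for any difference, 365 for Martinotti, 508 for interneuron-selective, 539 for CCK basket, 2321 for PV basket, 538 for upper chandelier, 469 for deep chandelier, 3264 for long-projecting, 51 for upper against deep chandelier, 944 for upper chandelier against PV basket and 4 for interneuron-selective against CCK basket; the weights ran from 0.385 for deep chandelier to 1.87 for long-projecting cells. Sex as a covariate gave 193 for Martinotti, 465 for interneuron-selective, 140 for CCK basket, 1977 for PV basket, 34 for upper chandelier, 1258 for deep chandelier, 597 for long-projecting, 23 for upper against deep chandelier, 5 for interneuron-selective against CCK basket and 59 for Martinotti against long-projecting, but libraries of PV basket cells, the only type with both labelled sexes, did not separate by sex, so this fit does not adjust for it. Without the 3 libraries the counts were 191 for upper chandelier, 245 for upper against deep chandelier and 388 for Martinotti against long-projecting. Splitting animal 14 by age gave 558 for upper chandelier, 1010 for upper against deep chandelier and 129 for upper chandelier against PV basket. With only the compared types in the fit the counts were 0 for upper against deep chandelier, 676 for upper chandelier against PV basket, 1 for interneuron-selective against CCK basket and 1900 for Martinotti against long-projecting, with few residual degrees of freedom.

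Library sums with the library number as a replicate block gave 1728 for PV basket, 480 for upper chandelier, 1101 for upper against deep chandelier, 530 for upper chandelier against PV basket, 466 for interneuron-selective against CCK basket and 931 for Martinotti against long-projecting. The same sums with no replicate block gave 8677 for any difference, 1877 for Martinotti, 2743 for interneuron-selective, 1793 for CCK basket, 3998 for PV basket, 989 for upper chandelier, 4766 for deep chandelier, 3071 for long-projecting, 2581 for upper against deep chandelier, 1560 for upper chandelier against PV basket, 1193 for interneuron-selective against CCK basket and 1865 for Martinotti against long-projecting. Libraries of an animal are not independent, and the numbers do not pair samples.

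Of 34 gene families 17 differed from matched lists, and 23 by Fisher's exact test without matching, 23 at an adjusted p of 0.01 and 15 without PV basket cells. Families above all matched lists in the assignment numbered 9, as with Pearson correlation, 8 with thinned cells and 5 with library sums, but the families changed: 7 of the 9 remained with Pearson correlation, 7 with thinned cells and 2 with library sums. List tests passed in 109 pairs, and in 33 with an estimated correlation.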

Other observations

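The following genes were chosen after their values were seen, and no test beyond those of the report was run on them. Crh and its binding protein gene Crhbp were highest in different types: Crh stood at 3689 CPM in CCK basket and 0.490 CPM in long-projecting cells, Crhbp at 10.3 and 5418 CPM. Tac1 had its highest mean in PV basket cells, at 823 ± 96.4 CPM (SD, n = 2), though deep chandelier animal 11 reached 832.4 CPM, and the gene of its receptor Tacr1 in long-projecting cells, at 1004 ± 152 CPM (SD, n = 4) against 0.662 CPM in CCK basket cells.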
